A study of Mus musculus with 6 samples.

How the data were processed

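The series holds single-cell RNA sequencing of lung tissue from male C57BL/6J mice aged 12 weeks, in 3 groups of 2 mice each: control (PBS), LPS at 1 mg/kg, and SLC activation (7 times) plus LPS. The series title names the subcoeruleus nucleus, and the labels call the activation SLC-Gq. Mice were assigned at random per the labels, and lungs were taken 3 days after treatment. Per the labels the tissue was digested with enzymes, dead cells were removed, libraries were made on the BD Rhapsody system and read on a DNBSEQ-T7 with 150 bp paired ends. The libraries are called control_1, control_2, LPS_1, LPS_2, SLC_1 and SLC_2 here, after the group and replicate number in the labels. When the 7 activations took place relative to LPS is not given in the sources used here, and no group with SLC activation alone is analysed here.

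The deposited values are UMI counts per gene and barcode, made by the authors from the reads. The tool is not given in the sources used here. The submitters' processing notes name the genome builds GRCm39 and mm39. Gene names were taken as given in the files, and no coordinates were used. The matrices are unfiltered, with 165547 to 253281 barcodes per library and 31589233 to 48641470 UMIs. Barcodes with at least 500 UMIs, at least 300 genes and under 20% mitochondrial UMIs were kept. Scrublet, run per library in scanpy 1.11.5 with an expected doublet rate of 0.06, called 1.73%, 1.58%, 0.554%, 2.21%, 0.0149% and 0.0696% of these from control_1 to SLC_2, and these were left out. All 6 libraries are under the expected rate, the 2 SLC libraries furthest, so its automatic threshold may not have worked there, which was not tested. Leaving out the top 6% of scores per library was added as an alternative.

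After these steps 12454, 12248, 13634, 11352, 13425 and 12929 cells remained, with a median of 1730, 1568, 1539, 2577.5, 1433 and 1133 UMIs and 8.81%, 7.99%, 1.43%, 2.79%, 1.66% and 1.23% mitochondrial UMIs. The kept cells hold 75.3%, 74.7%, 85.5%, 86.5%, 85.8% and 85.1% of all UMIs. Each share of cells has an exact binomial 95% interval, such as 15.7% to 17% for neutrophils in control_1 (16.3%). That interval covers the counting of cells and not the spread between mice. Between the 2 libraries of a group, chi-square per degree of freedom over genes was 32.3, 220 and 149, so replicates differ by more than counting noise and tests use the spread between libraries.

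All cells were normalized, log transformed, reduced to 40 principal components on 3000 variable genes chosen within libraries, and clustered together with leidenalg 0.10.2 at resolution 1 on 20 neighbours, without integration. Clusters were named from marker lists fixed before the data were examined. The naming rule was revised 2 times after the cluster tables were seen and before any test. A name now needs at least 3 markers detected in at least 10% of cells. Where the cluster's top 10 genes hold more markers of another class, that class is taken if they hold at least 3, and else the cluster stays unnamed. These changes named cluster 25 a club cell cluster and left cluster 4 unnamed. Names are therefore marker-based ("neutrophil" means neutrophil-like). Cluster 0, 1 of the neutrophil clusters, is led by interferon-induced genes such as Rsad2 and Ifit3. Neutrophils and alveolar macrophages of controls and of treated mice fall in different clusters, as given beside their values.

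UMI counts were summed per library over all kept cells and over each of 7 classes fixed beforehand with at least 20 cells in each library: neutrophil, monocyte, alveolar macrophage, T cell, NK cell, B cell and endothelial cell. Each of these 8 units was tested with edgeR 4.0.16 (TMM factors, low counts removed by filterByExpr, robust quasi-likelihood F test), with all 6 libraries in 1 fit and group as the only term. Adjusted p is the Benjamini-Hochberg value of this edgeR test over the genes of a unit, and a gene passes, rises or falls at adjusted p under 0.05. Shares were tested with edgeR on cells counted per class, with the library's total of kept cells as offset, adjusted over 17 classes with at least 10 cells per library on average. For 2 against 2 libraries an exact permutation test cannot give a two-sided p under 0.333, so the spread was pooled over genes or classes and the 3 groups. With so few mice the p-values of these edgeR tests speak for the spread between these mice. DESeq2 1.42.0 was run as an alternative.

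The named genes follow a rule written before the data were examined. Per comparison and unit they are the 2 largest rises and 2 largest falls among genes that pass, with at least 50 CPM in the higher group and no overlap of the libraries, leaving out predicted, Rik, mitochondrial, ribosomal, haemoglobin and immunoglobulin or T cell receptor segment genes. Where none passes, the 2 smallest unadjusted p are named with values and no call. This fallback was read as having no CPM limit. From each list come 2 to 4 members with the smallest p in the unit where the list moves most, and Adrb1, Il1b, Tnf, Il6, Il10, S100a8, Saa3, Lcn2, Cxcl2 and Fkbp5 are always looked at. An item of the same rule is not reported here. Some genes named by the rule are left to the figure or not printed. A fold against a group without counts is given as a lower bound against 3 counts, and against 1 to 3 counts as a ratio with its counting interval.

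Lists, also fixed beforehand, number 17: NF-kB and inflammatory cytokines, interferon-stimulated, acute phase and antimicrobial, MHC class II, MHC class I, adrenergic receptors and signalling, cAMP and CREB targets, glucocorticoid targets, dissociation and immediate early, cell cycle, alternative activation, cytotoxic effector, lymphocyte activation and checkpoint, endothelial adhesion, chemokine receptors and trafficking, oxidative phosphorylation, and genes of free RNA (markers of other lung cells). They were tested with camera in limma 3.58.1 on voom log2 CPM at a preset correlation between genes of 0.01, for lists with at least 5 tested members, adjusted over the 135 tests of a comparison. The same test with an estimated correlation stands beside each result. It has only the few degrees of freedom left by 6 libraries in 3 groups. Passing after adjusting over 135 tests was therefore hardly possible, and its failure does not show that correlation between genes explains a list result. The preset version takes its degrees of freedom from the number of genes. Its p-values compare genes and do not measure the spread between mice. "Adjusted over the list alone" counts members after adjusting over the list's own members. The free RNA list holds abundant transcripts of several lung cell types, among them S100a8 and S100a9 of neutrophils and Igkc and Ighm of B cells. In some units its members are thus the cells' own genes.

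Free RNA was estimated from the barcodes not kept. From control_1 to SLC_2 these include 1366, 901, 375, 173, 314 and 158 barcodes that failed only on mitochondrial UMIs. They are thus not empty droplets alone, and failed cells weigh more in controls. For each class the share of free RNA is a median over 5 or 7 reference genes of other classes. The values are the gene's level in the class over that in the barcodes not kept. Outside neutrophils and monocytes the reference genes are S100a8, S100a9, Retnlg, Hdc and Il1r2. In those classes the percent of S100a8 expected from free RNA is therefore not independent evidence. The reference genes for monocytes were changed after a first choice gave more than 100%. The free RNA share was 2.50% to 6.60% over the classes of LPS_2. It was 11.8% to 36.4% in alveolar macrophages, T cells and NK cells of the SLC libraries. After this difference was seen, the expected free RNA was subtracted from the class sums, which left almost no calls, and then genes with at least 50% of their level expected from free RNA were left out instead. Both are given in the closing section, in that order. A gene counts as prone by its expected share in the group where it is highest. Free RNA shares were low in LPS_2, so genes high after LPS count as prone less easily than genes high in controls. The split into higher and lower calls under this setting therefore partly follows from the rule.

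Alternatives chosen before the data were examined were other normalization (DESeq2's size factors in edgeR), no low-count filter, DESeq2, the replicate number as a block, a stricter cell filter (1000 UMIs, 500 genes, 10% mitochondrial), Scrublet calls kept, resolution 0.5, immune cells as the total, TMM factors over classes, an estimated correlation, and each library left out in turn. In the last, the group's remaining library is taken to vary like the other groups. The edgeR test was tested on simulated data with 200 changed genes per unit, built on the real libraries; in the whole library for LPS against control it found 69% of 4-fold and 11% of 2-fold changes, with 6 false calls among 86. Computation used R 4.3.3 and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Of the patterns weighed in the closing section, Mid1 was chosen after its values were seen, in place of neutrophil transcripts in T cells, which had been set down first and were not tested.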

Results

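Lung cells from 6 male C57BL/6J mice were compared, 2 each given PBS (control), LPS at 1 mg/kg, or LPS with activation of the subcoeruleus nucleus (SLC) 7 times. Lungs were taken on day 3. Of the barcodes in the 6 libraries, 11352 to 13634 per library were kept as cells, with a median of 1133 to 2577.5 UMIs and 647 to 1090.5 genes per cell. Levels are in CPM of UMI counts summed per library, as mean ± SD of n = 2 libraries, and log2 fold changes carry a standard error (SE). Cell class names rest on marker genes. The percent of a gene's level expected from free RNA is that in the group, of the 3, where the gene is highest. It is capped at 100% in each library, so an expectation above the observed level is not seen in it. Subtracting the expected free RNA from the class sums left 0 or 1 gene passing in each class and comparison. Each gene named below as risen or fallen showed no overlap between the libraries of its 2 groups. The rule for naming the largest changes asks for this, so it adds no weight to those calls.

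Neutrophils were the largest class after LPS. They made up 14.9 ± 2.02% of kept cells in controls, 52.6 ± 15.0% after LPS and 67.4 ± 3.13% after SLC activation plus LPS. The share of cells named interstitial macrophages, the macrophages of the lung's connective tissue, fell after LPS from 5.13 ± 0.341% to 0.397 ± 0.198% (log2 fold change −3.69, SE 0.848, adjusted p = 0.000549). Clustering was without integration, and alveolar macrophages of treated mice fell in another cluster than those of controls. Whether interstitial macrophages of treated mice moved to another cluster, such as cluster 4 below, was not tested. Lymphatic endothelial cells fell from 0.562 ± 0.114% to 0.0756 ± 0.055% (−2.90, SE 0.867, adjusted p = 0.00883). Group 2 innate lymphoid cells fell from 1.57 ± 0.188% to 0.333 ± 0.139% (−2.24, SE 0.805, adjusted p = 0.0292) and fibroblasts from 20 ± 3.94% to 4.5 ± 2.49% (−2.15, SE 0.787, adjusted p = 0.0292). The neutrophil share did not pass over all 6 libraries (log2 fold change 1.82, SE 0.778, adjusted p = 0.0656), and passed without LPS_2 (adjusted p = 0.00597). In LPS_1 neutrophils were 63.2% of cells and in LPS_2 41.9%. An unnamed group of cells, cluster 4, went from 0.101 ± 0.0413% to 8.87 ± 6.50% (log2 fold change 6.44, SE 0.975, adjusted p = 3.95e-07). Its leading genes include the monocyte markers Ly6c2 and Ms4a4c, with Monocyte the next class by marker score, and Saa3, Arg1 and Inhba, which themselves differ between the groups, so its share is not given as a change of a cell population.

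Of 17 classes, 5 changed in share after LPS against control (1 higher, 4 lower; 6 at unadjusted p under 0.05). The count was 2 without either control library and 14 without LPS_2, and 5 without LPS_1 or either SLC library. With TMM factors over classes, which set the typical class to no change, 3 passed (2 higher, 1 lower): neutrophils (adjusted p = 0.0279), cluster 4 and interstitial macrophages (−2.41, adjusted p = 0.00925). The falls of lymphatic endothelial cells (−1.69, adjusted p = 0.0772), innate lymphoid cells (−0.93, adjusted p = 0.16) and fibroblasts (−0.89, adjusted p = 0.133) ended there.

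After SLC activation plus LPS against control, 12 of 17 changed (2 higher, 10 lower). Neutrophils rose (log2 fold change 2.18, SE 0.787, adjusted p = 0.0149). B cells, which make antibody, fell from 12.1 ± 1.17% to 2.23 ± 1.49% (−2.44, adjusted p = 0.00986). Interstitial macrophages (−4.13, adjusted p = 8.94e-05), lymphatic endothelial cells (−4.82, adjusted p = 8.94e-05), innate lymphoid cells (−3.22, adjusted p = 0.00154) and fibroblasts (−2.64, adjusted p = 0.00619) fell as well. This count was 3 without control_1, 4 without control_2, 6 without SLC_1, 5 without SLC_2 and 16 without either LPS library. With TMM factors over classes 4 passed (2 higher, 2 lower), interstitial macrophages (adjusted p = 0.0127) and lymphatic endothelial cells (adjusted p = 0.0153) being the falls, and those of B cells (−0.34, adjusted p = 0.746), innate lymphoid cells (−1.22, adjusted p = 0.0829) and fibroblasts (−0.68, adjusted p = 0.212) ended. Under the stricter cell filter 5 of 16 passed (1 higher, 4 lower), without the neutrophil rise (1.70, adjusted p = 0.0862) or the B cell fall (−1.38, adjusted p = 0.162). That filter took B cells of controls from 1613 and 1384 to 186 and 207, or 2.80% and 3.13% of cells, against 0.306% and 1.98% in the SLC libraries. Median mitochondrial percent was 8.81 and 7.99 in controls and 1.23 to 2.79 in treated libraries. Shares of a library sum to 100, so a higher neutrophil share lowers the others. The limit given above for interstitial macrophages, a possible move between clusters, holds here too.

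**Figure D1:**
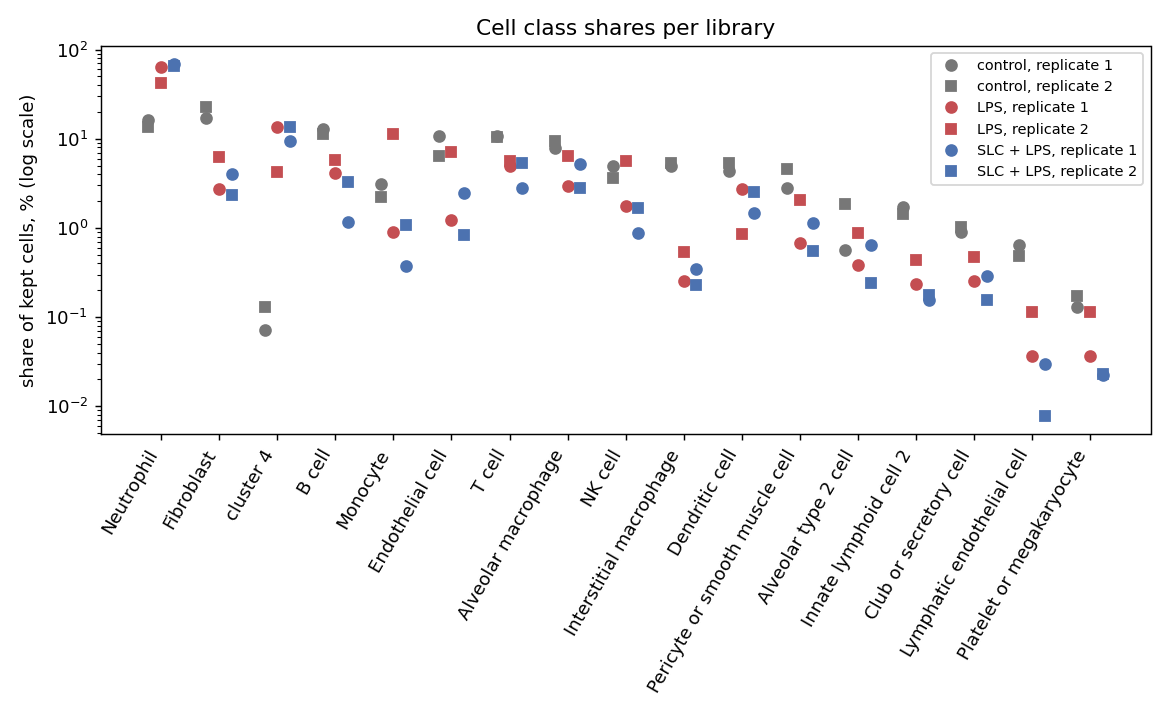
Percent of kept cells in each marker-based class, on a log axis, with 1 point per library (2 libraries each for control, LPS, and SLC activation plus LPS). Shares of a library sum to 100.

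Between SLC activation plus LPS and LPS alone, 0 of 17 classes passed in edgeR, with 1 at unadjusted p under 0.05. That class was the monocyte, at 0.724 ± 0.497% against 6.16 ± 7.45% (log2 fold change −3.09, SE 0.997, adjusted p = 0.105). The LPS mean joins 0.895% in LPS_1 and 11.4% in LPS_2. Without LPS_1 4 classes passed, among them monocytes (−3.98, adjusted p = 1.52e-05) and NK cells (−2.14, adjusted p = 0.0131), while without LPS_2 the monocyte log2 fold change was −0.31 (adjusted p = 0.855). In the monocyte class 62.4% of cells had a Treml4 UMI, 58.0% Adgre4, 45.7% Ly6c2 and 31.4% Ccr2. This class is cluster 14 alone, led by Cd300e, Spic and Adgre4, and may not hold all lung monocytes. Counted with cluster 4, which carries Ly6c2, it makes 14.4% and 15.7% of cells after LPS against 9.70% and 14.5% after SLC activation plus LPS, so the large difference is absent from the sum, which was not tested.

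LPS changed genes of inflammation in the whole library. Nos2, the inducible nitric oxide synthase, rose from 0.602 ± 0.324 to 180 ± 11.8 CPM (log2 fold change 8.19, SE 0.629, adjusted p = 0.0146). Saa3, an acute phase protein, rose from 5.16 ± 0.752 to 1449 ± 1240 CPM (8.13, SE 0.798, adjusted p = 0.0146). Il1b, the cytokine interleukin 1 beta, went from 2287 ± 262 to 10526 ± 84.5 CPM (2.20, SE 0.239, adjusted p = 0.0159). Its antagonist Il1rn rose from 315 ± 19.7 to 2564 ± 1000 CPM (3.03, SE 0.329, adjusted p = 0.0162). The neutrophil gene S100a8 rose from 684 ± 320 to 3944 ± 1378 CPM (2.53, SE 0.459, adjusted p = 0.0311). Lcn2, which binds bacterial iron carriers, rose from 55.6 ± 22.7 to 762 ± 479 CPM (3.78, SE 0.567, adjusted p = 0.0236). Cd209a, a marker of dendritic cells, fell from 62.0 ± 2.21 to 1.09 ± 0.174 CPM (−5.82, SE 0.533, adjusted p = 0.0146). Clec3b, a stromal gene, fell from 152 ± 32.9 to 11.8 ± 8.04 CPM (−3.69, SE 0.610, adjusted p = 0.0266). These values mix a change of cell classes with a change inside them.

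Of 17930 genes, 1438 passed in the whole library (728 higher, 710 lower). Each call, and so each gene named in the paragraph above, ended without either control library: 0 genes passed in both cases, with adjusted p for Nos2 0.124 without control_1 and 0.163 without control_2, and for Saa3 0.131 and 0.189. The count was 2059 without LPS_1, 2864 without LPS_2, 775 without SLC_1 and 785 without SLC_2; without SLC_1 S100a8 was at adjusted p = 0.0502. Leaving out a library leaves a group with 1 library, which is then taken to vary like the others. Adrb1, the beta-1 adrenergic receptor, fell from 38.4 ± 3.90 to 11.6 ± 4.33 CPM (−1.73, SE 0.315, adjusted p = 0.0312), a call that also ended without SLC_1 (adjusted p = 0.0618) or SLC_2 (0.0585). Under the stricter cell filter Adrb1 (−1.56) and S100a8 (2.29) did not pass. Tnf (1.27, adjusted p = 0.0609), Il6 (1.52, adjusted p = 0.0729), Il10 (2.14, adjusted p = 0.0975), Cxcl2 (1.06, adjusted p = 0.217) and the glucocorticoid target Fkbp5 (0.22, adjusted p = 0.687) did not pass.

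In neutrophils LPS raised Nos2, Tnf and Rab15, and Inmt fell. Nos2 went from 0.704 ± 0.995 to 263 ± 140 CPM (log2 fold change 8.25, SE 0.789, adjusted p = 0.00269). Tnf, the cytokine tumour necrosis factor, rose from 1002 ± 34.6 to 4216 ± 931 CPM (2.07, SE 0.407, adjusted p = 0.0237). Rab15, a small GTPase of vesicle traffic, stood at 77.6 ± 16.7 CPM after LPS, from 1675 counts against 1 in controls, a ratio of 345 (95% counting interval 61.8 to 13627; adjusted p = 0.00269). Adora2b, an adenosine receptor, had 1584 counts against 1 (ratio 326, 58.4 to 12887; adjusted p = 0.00336). Inmt, a fibroblast gene, fell from 213 ± 30.1 to 8.29 ± 2.34 CPM (−4.68, SE 0.397, adjusted p = 0.00262), with 67.4% of its level expected from free RNA. Saa3 rose (6.07, SE 0.653, adjusted p = 0.00359, 45.2% expected from free RNA), and Scgb3a2, a club cell gene (−4.81, adjusted p = 0.0129, 100%), and Adrb1 (−3.06, SE 0.644, adjusted p = 0.0309, 100%) fell. Il1b (0.15, adjusted p = 0.863) and S100a8 (0.55, adjusted p = 0.59) did not pass within the class.

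In this class 651 of 13297 genes passed (343 higher, 308 lower), 12 without control_1, 6 without control_2, 1800 without LPS_1, 904 without LPS_2, 445 without SLC_1 and 481 without SLC_2. With free-RNA-prone genes left out 350 passed, 302 higher and 48 lower. Genes high after LPS are less easily left out, as LPS_2 held little free RNA. This split therefore does not show that the rises are free of it or that the falls come from it. Nos2, Rab15 and Inmt passed whichever library was left out (Nos2 adjusted p 0.000338 to 0.0422). The calls of Tnf (adjusted p = 0.269 and 0.268) and Saa3 (0.0665 and 0.0882) ended without control_1 and control_2, that of Adora2b without control_1 (0.0518), that of Adrb1 without control_1 (0.189), control_2 (0.206) or SLC_1 (0.052), and that of Scgb3a2 without control_2 (0.118), LPS_1 (0.126) or LPS_2 (0.19). Different clusters hold this class in the groups: cluster 6 held 91.7% and 93.3% of neutrophils in controls, clusters 0, 2 and 1 held 39.4%, 30.0% and 24.8% in LPS_1, and cluster 10 held 58.3% in LPS_2. The free RNA share of neutrophils was 27.7%, 23.7%, 26.3%, 3.56%, 18.8% and 35.5% from control_1 to SLC_2.

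**Figure D2:**
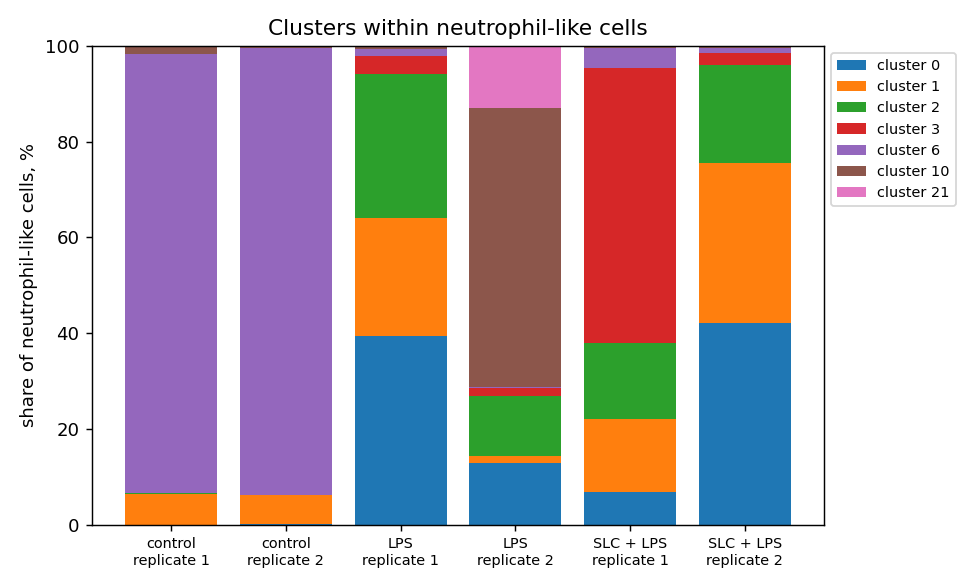
Which clusters make up the neutrophil class in each library: percent of neutrophil-like cells by cluster, stacked, for the 6 libraries. Cluster numbers come from 1 joint clustering of all libraries.

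In alveolar macrophages Ly6i, Saa3, Lcn2 and Il1b rose after LPS. Ly6i, a surface protein of the Ly6 family, went from 1.34 ± 0.895 to 1208 ± 893 CPM (log2 fold change 9.80, SE 1.40, adjusted p = 0.0246), Saa3 from 2.21 ± 1.10 to 513 ± 571 CPM (7.84, SE 1.15, adjusted p = 0.025, 29.8% expected from free RNA). Lcn2 went from 8.41 ± 1.02 to 256 ± 277 CPM (4.92, SE 0.907, adjusted p = 0.0386) and Il1b from 1158 ± 34.4 to 3835 ± 1500 CPM (1.73, SE 0.324, adjusted p = 0.0402). Adrb1 fell from 95.9 ± 10.2 to 13.5 ± 4.98 CPM (−2.84, SE 0.335, adjusted p = 0.0221), with 8.55% expected from free RNA. Inmt fell (−4.84, adjusted p = 0.02, 42.9% free RNA), as did Scgb3a2 (−4.92, adjusted p = 0.0356, 100%). The total was 398 of 11695 genes (220 higher, 178 lower). Without either control library 0 passed (Adrb1 adjusted p = 0.146 and 0.182), and 1731 passed without LPS_1, 983 without LPS_2, 227 without SLC_1 (164 higher, 63 lower) and 235 without SLC_2 (168 higher, 67 lower). With free-RNA-prone genes left out 258 passed, 187 higher and 71 lower. The call of Ly6i also ended without LPS_1 (adjusted p = 0.065) or LPS_2 (0.0562), and those of Il1b (0.0635, 0.0598) and Lcn2 (0.0637, 0.0614) without SLC_1 or SLC_2, as did that of Scgb3a2 (0.0628, 0.0595), which ended without LPS_2 too (0.0974). Il1b and Scgb3a2 did not pass under the stricter cell filter, nor Ly6i, Saa3 and Lcn2 without a low-count filter. Cluster 16 held 92.3% and 92.5% of these cells in controls, and cluster 12 held 98.8%, 98.3%, 99.3% and 99.5% in the treated libraries.

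In monocytes, Nos2 had 434 counts after LPS and 0 in controls (at least 40.4-fold; adjusted p = 0.0203, 30.2% expected from free RNA) and Cxcl9, an interferon-induced chemokine, 719 against 1 (ratio 201, 35.9 to 7946; adjusted p = 0.0335, 44.4%). Ltbp4 (adjusted p = 0.0203) and Abca8a (−5.75, adjusted p = 0.0225) fell, with 64.5% and 91.3% expected from free RNA. The count was 30 of 5798 genes (8 higher, 22 lower; 30 higher and 31 lower by DESeq2), 19 without control_1, 2 without control_2, 891 without LPS_1 and 12 without LPS_2. With free-RNA-prone genes left out it was 5, 4 higher and 1 lower. The calls of Nos2 (adjusted p = 0.068), Cxcl9 (0.0767), Abca8a (0.0797) and Ltbp4 (0.0804) ended without LPS_2. Those of Cxcl9 ended also without control_1 (0.459) or control_2 (0.218) and of Abca8a (0.504) and Ltbp4 (0.497) without control_2. Nos2 (8.95) did not pass with the top 6% of doublet scores left out, nor Cxcl9 by DESeq2 (7.16) or with free-RNA-prone genes left out (7.14). In NK cells, the innate killer lymphocytes, Pim2, a survival kinase, rose from 89.0 ± 23.6 to 745 ± 306 CPM (3.06, SE 0.403, adjusted p = 0.0304). The interferon-induced GTPase Gbp5 rose from 14.7 ± 0.952 to 133 ± 41.0 CPM (SE 0.514, adjusted p = 0.046). From free RNA 0.37% and 16.7% of these levels is expected. The cell division genes Rrm2 (146 ± 12.8 against 19.5 ± 1.5 CPM, 2.88) and Tpx2 (53.6 ± 4.52 against 7.89 ± 1.89 CPM, 2.79) rose with adjusted p = 0.046. NK cells had 19 calls (10 higher, 9 lower), 15 without control_1, 4 without control_2, 787 without LPS_1 and 252 without LPS_2. The calls of Gbp5 (adjusted p = 0.193, 0.207), Rrm2 (0.193, 0.264) and Tpx2 (0.38, 0.256) ended without control_1 and control_2, that of Tpx2 also without SLC_1 (0.051) or SLC_2 (0.0703), and that of Pim2 without control_2 (0.0679). The first 3 also ended under the stricter cell filter (3.22, 2.70 and 2.71), which left 6 calls, and with free-RNA-prone genes left out, which left 4, and Tpx2 with the top 6% of doublet scores left out.

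Endothelial cells had 3 calls. Ankrd37, a gene induced by low oxygen, rose from 8.43 ± 0.578 to 88.4 ± 0.473 CPM (log2 fold change 3.36, SE 0.379, adjusted p = 0.0341, 1.89% expected from free RNA), ending without control_1 (adjusted p = 0.186) or control_2 (0.234). Gsn fell from 969 ± 346 to 131 ± 2.79 CPM (−2.89, adjusted p = 0.0367, 50.5%), ending without control_2 (0.234), SLC_1 (0.0723) or SLC_2 (0.0716). The alveolar type 2 cell gene Sftpc fell (−3.88, adjusted p = 0.0341, 100%), ending without control_1 (0.0772) or control_2 (0.14). In T cells Timp3, an inhibitor of matrix proteases, fell from 119 ± 28.1 to 12.4 ± 0.728 CPM (−3.26, SE 0.334, adjusted p = 0.0331, 100% expected from free RNA), ending without control_2 (0.155), SLC_1 (0.131) or SLC_2 (0.119). In B cells Inmt fell from 191 ± 65.0 to 4.15 ± 3.91 CPM (−5.32, SE 0.525, adjusted p = 0.0309, 52.9%). These were the single calls in T cells (0 without control_2, SLC_1 or SLC_2, 8 without control_1, 753 without LPS_1, 173 without LPS_2) and B cells (9 without control_1, 63 without LPS_1, 8 without LPS_2, 3 without SLC_1 or SLC_2). Endothelial cells had 0 without control_2, 1230 without LPS_1, 175 without LPS_2 and 9 without SLC_1 or SLC_2. Under the stricter cell filter they had 0, with Ankrd37 at 3.18, Gsn at −3.09 and Sftpc at −4.29. With free-RNA-prone genes left out T, B and endothelial cells had 0 calls, Timp3, Inmt, Gsn and Sftpc being among the genes left out and Ankrd37 not passing.

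Interferon-stimulated genes were higher as a list in all 8 units tested after LPS (the whole library and 7 classes). In the whole library 17 of 32 members rose (26 adjusted over the list alone), with a median log2 fold change of 2.82 (adjusted p = 3.79e-14, adjusted p = 0.507 with an estimated correlation). In alveolar macrophages 16 rose (26 adjusted over the list alone; median 3.42, adjusted p = 6.3e-16, adjusted p = 0.475 with an estimated correlation), and in neutrophils 17 (23 adjusted over the list alone, median 2.42, adjusted p = 0.507 with an estimated correlation). T cells had no member passing over all genes and 24 of 29 adjusted over the list alone (median 1.77, adjusted p = 8.47e-23, adjusted p = 0.475 with an estimated correlation), among them Ly6a at 1113 ± 148 against 237 ± 0.916 CPM (2.23, adjusted p = 0.106). MHC class I genes, which present antigen to killer T cells, were higher in 8 units, with 8 of 17 members rising in the whole library (13 adjusted over the list alone; median 1.78, adjusted p = 0.507 with an estimated correlation). In endothelial cells 0 members passed and 13 did adjusted over the list alone (median 1.47, adjusted p = 6.74e-15, adjusted p = 0.475 with an estimated correlation), with Psmb9 at 2.26 and Tapbp at 1.80 (adjusted p = 0.0872 each).

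NF-kB and inflammatory cytokine genes were higher in 6 units. In the whole library 8 of 22 rose (15 adjusted over the list alone; median 1.38, adjusted p = 2.06e-10, adjusted p = 0.475 with an estimated correlation). Among them were Sod2, a mitochondrial superoxide dismutase (1946 ± 73.4 against 327 ± 18.9 CPM, adjusted p = 0.0146), and Clec4e, a receptor for fungal and mycobacterial glycolipids (4306 ± 276 against 774 ± 152 CPM; adjusted p = 0.0197). Acute phase and antimicrobial genes were higher in 2 units, the whole library (7 of 18 rose, 12 adjusted over the list alone; median 1.90, adjusted p = 0.475 with an estimated correlation) and alveolar macrophages (adjusted p = 0.8 with an estimated correlation). Cell cycle genes were higher in 4 units. In alveolar macrophages 11 of 20 rose (18 adjusted over the list alone; median 1.53, adjusted p = 0.475 with an estimated correlation), and in NK cells 2 of 19 (13 adjusted over the list alone; median 1.97, adjusted p = 0.475 with an estimated correlation). Adrenergic receptor and signalling genes were lower in 3 units, neutrophils (median −0.70, 1 of 11 fell, 3 adjusted over the list alone), T cells and endothelial cells (adjusted p = 0.475 with an estimated correlation in each). Of the other lists, cytotoxic effector genes were higher in 2 units (T cell median 0.76, adjusted p = 0.000118, adjusted p = 0.507 with an estimated correlation) and lymphocyte activation genes higher in 2 and lower in 1 (adjusted p = 0.475 with an estimated correlation). Chemokine receptor and trafficking genes were higher in 3 (whole library median 0.67, adjusted p = 0.00505, adjusted p = 0.661 with an estimated correlation) and dissociation and immediate early genes higher in endothelial cells (0.46, adjusted p = 0.011, adjusted p = 0.661 with an estimated correlation). Glucocorticoid targets were lower in 2 (B cell median −0.68, adjusted p = 0.00119, adjusted p = 0.507 with an estimated correlation). Genes of the free RNA list were lower in all 8 units, with a median of −3.58 in neutrophils and −3.46 in monocytes (adjusted p = 8.8e-09, adjusted p = 0.475 with an estimated correlation). The list holds S100a8 and S100a9, the neutrophils' own genes, and Igkc and Ighm of B cells. Its fall thus does not show that free RNA, or markers of other cells, fell in each unit. MHC class II, cAMP and CREB target, alternative activation, endothelial adhesion and oxidative phosphorylation lists passed in 0 units. In all 50 of 135 list tests passed (36 up, 14 down), with 62 at unadjusted p under 0.05. Under an estimated correlation, with its few degrees of freedom, 0 passed. The down calls vary most: 36 up and 30 down without LPS_1, 51 up and 11 down without LPS_2, 35 up and 10 down of 108 tests with free-RNA-prone genes left out, and 33 up and 7 down of 125 with free RNA subtracted. In 19 tests, none of them passing, median, mean and test differed in sign.

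Between SLC activation plus LPS and LPS alone, 2 genes differed in the classes tested. Slc15a2, a transporter of small peptides, was at 17.1 ± 6.27 CPM in neutrophils against 0.297 ± 0.206 after LPS (log2 fold change 5.88, SE 0.581, adjusted p = 0.0183), and at 30.3 and 39.3 CPM in the 2 controls. Mid1, a ubiquitin ligase that binds microtubules, was at 142 ± 12.1 CPM in T cells against 7.75 ± 3.42 (SE 0.363, adjusted p = 0.00764), with controls at 10.449 and 9.842. From free RNA 64.1% of the Mid1 level in T cells is expected, and 25.2% of the Slc15a2 level in the neutrophils of controls, where it was highest. Neutrophils of SLC_1 and SLC_2 had 21.5 and 12.7 CPM of Slc15a2, with 39.6 and 22.8 CPM in barcodes not kept. Their free RNA shares were 18.8% and 35.5%, so more of the Slc15a2 level is expected from free RNA there than in controls. Of the cytokine and acute phase genes fixed beforehand none passed.

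The call of Slc15a2 ended without control_1 (adjusted p = 0.0544), control_2 (0.0629) or SLC_1 (0.0872), and that of Mid1 without SLC_1 (0.424) or SLC_2 (0.17). In edgeR the whole library, monocytes, alveolar macrophages, NK cells, B cells and endothelial cells had 0 calls each, with 489, 393, 269, 395, 733 and 702 genes at unadjusted p under 0.05 and 17, 1, 2, 1, 2 and 7 calls by DESeq2. Neutrophils and T cells had 413 and 384, and 12 and 2 by DESeq2. The counts hang on LPS_1: without it 563 genes passed in neutrophils, 549 in monocytes, 379 in alveolar macrophages, 720 in T cells, 534 in NK cells, 101 in B cells and 1044 in endothelial cells, and 0 in the whole library. Without SLC_1 65 passed in B cells and 0 in each other unit. Without SLC_2 4 passed in neutrophils and 0 in T cells, and without LPS_2 1 and 2. Without either control library, neutrophils had 0, T cells 2 and monocytes 1. Without LPS_1 the LPS group is LPS_2 alone. Cluster 10 held 58.3% of neutrophils in LPS_2 against 0.58% in LPS_1, and monocytes were 11.4% of cells against 0.895%. The counts without LPS_1 thus set 1 library, unlike the other of its group, against the SLC libraries. In simulated data a 4-fold change in single genes was found in 45% of cases in neutrophils and 71% in T cells in this comparison. A 2-fold change was found in 2% and 10%, so a count near 0 does not show that the groups are alike.

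Genes with large differences that did not pass include Mid1 in neutrophils (30.7 CPM, 3.67, adjusted p = 0.0574), monocytes (4.75, adjusted p = 0.192) and NK cells (3.59, adjusted p = 0.358), with 100%, 57.6% and 97.0% expected from free RNA. Ifit2, an interferon-induced protein, had 416 counts in monocytes after LPS and 1 after SLC activation plus LPS (ratio 37.1, 6.63 to 1470; adjusted p = 0.192). In alveolar macrophages H2-T23, a nonclassical MHC molecule, was at 18.9 ± 2.21 against 99.4 ± 5.51 CPM (−2.39, adjusted p = 0.967). In the whole library Il6, a fever-inducing cytokine, was at 77.9 ± 21.1 against 250 ± 132 CPM (−1.68, adjusted p = 0.923). Tnf (−0.41), Il1b (−0.16), Il10 (−0.77), Saa3 (0.60), Lcn2 (0.58), Cxcl2 (0.66), Fkbp5 (0.47) and Adrb1 (−0.34) had adjusted p = 0.923, and S100a8 0.926 (−0.28).

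The p-values of the list tests compare genes and do not measure the spread between mice. As lists, interferon-stimulated genes were lower after SLC activation plus LPS than after LPS in 6 of 8 units. The median log2 fold change was −1.02 in neutrophils (adjusted p = 1.21e-16, adjusted p = 0.595 with an estimated correlation), where no member passed over all genes or adjusted over the list alone, and −1.53 in endothelial cells (adjusted p = 0.595 with an estimated correlation, 1 member fell adjusted over the list alone). Irgm1, an interferon-induced GTPase, was at 105 ± 73.8 against 371 ± 143 CPM in neutrophils (−1.83, adjusted p = 0.994), Rtp4 at −1.66 and Gbp3 at −1.53. Mean log2 levels of the list in neutrophils were 5.16 in SLC_1 and 6.96 in SLC_2, against 6.96 and 7.32 in the LPS libraries. MHC class I genes were lower in 6 units, in endothelial cells with a median of −0.90 (adjusted p = 1.3e-09, adjusted p = 0.595 with an estimated correlation; 4 fell adjusted over the list alone). Cytotoxic effector genes were lower in 6 of 7 units (whole library median −1.41, adjusted p = 4.33e-10, adjusted p = 0.595 with an estimated correlation), with the granule protease Gzma at 81.0 ± 61.2 against 435 ± 420 CPM (adjusted p = 0.923). NK cells, which express these genes, were 5.62% of cells in LPS_2, 1.78% in LPS_1, and 0.886% and 1.67% in the SLC libraries. MHC class II genes were lower in 2 units, in monocytes with a median of −0.86 (adjusted p = 0.00108, adjusted p = 0.595 with an estimated correlation; 3 fell adjusted over the list alone), with Cd74 at 333 against 739 CPM (−1.14, adjusted p = 0.721).

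Acute phase genes were higher in 6 units and lower in neutrophils (NK cell median 1.02, adjusted p = 2.31e-08, adjusted p = 0.595 with an estimated correlation), with Steap4 in NK cells at 49.6 against 10.2 CPM (2.38, adjusted p = 0.852, 97.8% expected from free RNA). NF-kB genes were lower in neutrophils, monocytes and alveolar macrophages and higher in T, NK and B cells (NK cell adjusted p = 0.00062, adjusted p = 0.595 with an estimated correlation). The calls of the 3 lymphocyte classes ended once free-RNA-prone genes were left out (adjusted p = 0.53, 0.11 and 0.33). Alternative activation genes were higher in 5 units (B cell median 1.02, adjusted p = 0.00463), glucocorticoid targets in 5 (NK cell median 0.43, adjusted p = 0.00542) and immediate early genes in 3 (B cell median 0.67, adjusted p = 2.62e-05), none with an estimated correlation (lowest adjusted p = 0.595). Cell cycle genes were lower in NK cells (−0.85, adjusted p = 7.22e-08, adjusted p = 0.595 with an estimated correlation) and higher in 2 other units. Chemokine receptor genes were lower in 2 units (neutrophil median −0.60, adjusted p = 0.000508) and higher in 1. Oxidative phosphorylation genes were higher in 2 (B cell 0.62, adjusted p = 0.000154), lymphocyte activation genes lower in 2 (whole library −0.32, adjusted p = 0.00452) and cAMP and CREB targets lower in the whole library (−0.38, adjusted p = 0.0414). With an estimated correlation the lowest adjusted p over these 4 lists was 0.595. Genes of free RNA were higher in 3 units and lower in 1 (monocyte median 1.02, adjusted p = 0.000902, and adjusted p = 0.595 or more with an estimated correlation). Adrenergic and endothelial adhesion lists passed in 0 units. In all 61 of 135 tests passed (30 up, 31 down), with 76 at unadjusted p under 0.05. Under an estimated correlation, with its few degrees of freedom, 0 passed. The split hangs on single libraries: 8 up and 48 down without LPS_2, 27 up and 11 down without SLC_1, 22 up and 41 down without SLC_2, 44 up and 25 down without LPS_1. It moves with free RNA too: 12 up and 28 down of 108 tests with free-RNA-prone genes left out, and 15 up and 24 down of 125 with free RNA subtracted. For alternative activation genes in NK cells the median is 0.36, the mean −0.14 and the test up, and in 13 further tests, none passing, these signs differed.

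Against control, SLC activation plus LPS raised Saa3 in the whole library to 2196 ± 291 CPM (log2 fold change 8.73, SE 0.818, adjusted p = 0.0135) and Ly6i from 9.10 ± 1.64 to 1384 ± 1331 CPM (7.25, SE 0.919, adjusted p = 0.0175). Il1b was at 9391 ± 329 CPM (2.04, SE 0.238, adjusted p = 0.0148), S100a8 at 3257 ± 1045 (2.25, SE 0.454, adjusted p = 0.0331) and Lcn2 at 1135 ± 328 (4.35, SE 0.583, adjusted p = 0.0189), and these 3 rose too. Cd209a (−5.13, SE 0.514, adjusted p = 0.0136), Timd4, a macrophage receptor for dying cells (52.6 ± 15.0 to 2.11 ± 0.330 CPM, −4.64, adjusted p = 0.0293), and Adrb1 (to 9.16 ± 0.0655 CPM, −2.07, SE 0.319, adjusted p = 0.0227) fell. Tnf (0.86, adjusted p = 0.119), Il6 (−0.16, adjusted p = 0.813), Il10 (1.37, adjusted p = 0.201), Cxcl2 (1.73, adjusted p = 0.0695) and Fkbp5 (0.69, adjusted p = 0.174) did not pass. Of 17930 genes 2261 passed (950 higher, 1311 lower). Each of these calls ended without control_1, control_2 or SLC_2, where 0 genes passed (Saa3 adjusted p = 0.118, 0.149 and 0.0805), and 144 passed without SLC_1, where Timd4 (0.119), Adrb1 (0.0886), S100a8 (0.0762) and Lcn2 (0.0582) did not. S100a8 (1.93) did not pass under the stricter cell filter either. Without LPS_1 4975 and without LPS_2 5014 passed.

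In neutrophils Saa3 rose to 797 ± 208 CPM (log2 fold change 6.53, SE 0.664, adjusted p = 0.0036, 45.2% expected from free RNA) and Nos2 to 68.7 ± 26.2 CPM (6.31, SE 0.775, adjusted p = 0.00724). Cxcl9 had 2869 counts against 2 (ratio 262, 72.4 to 2162; adjusted p = 0.00926, 44.6%) and Adora2b 1414 against 1 (ratio 258, 46.2 to 10194; adjusted p = 0.00363). Inmt fell (−4.05, SE 0.384, adjusted p = 0.00363), and Tnf (1.45, adjusted p = 0.0704) and Adrb1 (−2.33, adjusted p = 0.0642) did not pass. The count was 444 of 13297 (246 higher, 198 lower; 444 higher and 603 lower by DESeq2), 0 without either control library, 123 without SLC_1 (111 higher, 12 lower), 58 without SLC_2 (50 higher, 8 lower), 1915 without LPS_1 and 1912 without LPS_2. With free-RNA-prone genes left out 291 passed, 228 higher and 63 lower. The named calls ended without control_1 and control_2 (Nos2 and Saa3 adjusted p = 0.0791 and 0.085, Cxcl9 0.141 and 0.125, Adora2b and Inmt 0.0791 and 0.0502). Cluster 3 held 57.4% of neutrophils in SLC_1 and cluster 0 42.0% in SLC_2, against cluster 6 in controls.

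In alveolar macrophages Ly6i rose to 1729 ± 1928 CPM (log2 fold change 10.32, SE 1.42, adjusted p = 0.0255) and Saa3 to 838 ± 302 (8.55, SE 1.18, adjusted p = 0.0255). Lcn2 rose to 602 ± 160 (6.16, SE 0.955, adjusted p = 0.0317, 18.1% expected from free RNA) and S100a8 from 76.6 ± 12.8 to 750 ± 563 CPM (3.29, adjusted p = 0.0353, 52.0%). S100a8 is 1 of the reference genes that set the free RNA share of this class, so its 52.0% is not independent evidence. The mitotic genes Ccna2 (29.2 ± 4.27 to 106 ± 17.2 CPM, 1.86, SE 0.263, adjusted p = 0.0282), Cdk1 (29.7 ± 8.41 to 107 ± 18.3 CPM, 1.85, adjusted p = 0.0317) and Birc5 (68.5 ± 13.7 to 210 ± 8.31 CPM, 1.62, adjusted p = 0.0317) rose. Kcnip4 fell from 370 ± 18.6 to 18.9 ± 0.0622 CPM (−4.29, SE 0.445, adjusted p = 0.0172). Spag11b, an antimicrobial peptide gene, fell from 76.9 ± 21.3 to 1.37 ± 0.215 CPM (−5.75, adjusted p = 0.0402), and Adrb1 from 95.9 ± 10.2 to 20.7 ± 3.44 CPM (−2.22, SE 0.326, adjusted p = 0.0305). The total was 384 of 11695 genes (201 higher, 183 lower), with 0 without either control library, 100 without SLC_1 (93 higher, 7 lower), 4 without SLC_2 (4 higher), 2069 without LPS_1 and 2089 without LPS_2. With free-RNA-prone genes left out 301 passed, 181 higher and 120 lower. Each named call ended without control_1, control_2 or SLC_2 (Kcnip4 adjusted p = 0.148, 0.13 and 0.107; Ly6i 0.26, 0.239 and 0.0575), and those of Kcnip4 (0.0524), Adrb1 (0.136), Lcn2 (0.0583), Spag11b (0.184), Ccna2 (0.0942), Cdk1 (0.123) and Birc5 (0.102) without SLC_1. Without a low-count filter Ly6i, Saa3, Lcn2 and Spag11b did not pass. Cluster 16 holds the class in controls and cluster 12 in the treated libraries.

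In T cells Mid1 rose from 10.1 ± 0.429 to 142 ± 12.1 CPM (log2 fold change 3.79, SE 0.340, adjusted p = 0.0106, 64.1% expected from free RNA), and Timp3 fell to 13.8 CPM (−3.15, adjusted p = 0.0363, 100%). These calls ended without control_2 (adjusted p = 0.162 and 0.201), SLC_1 (0.191 and 0.301) or SLC_2 (0.454 and 0.898). Those were the 2 calls in T cells, 4 without control_1, 0 without control_2, SLC_1 or SLC_2, 323 without LPS_1 and 326 without LPS_2. In NK cells Mid1 (2.64 ± 1.56 to 78.3 ± 0.516 CPM, 4.70, SE 0.641, adjusted p = 0.0202), S100a8 (63.6 ± 15.9 to 644 ± 132 CPM, 3.33, SE 0.475, adjusted p = 0.04) and Fpr2, a formyl peptide receptor of phagocytes (11.8 ± 0.761 to 150 ± 2.83 CPM, 3.66, SE 0.387, adjusted p = 0.00758), rose. S100a8 is 1 of the reference genes that set the free RNA share of NK cells, so its percent is not independent evidence. From free RNA 97.0%, 96.7% and 100% of the levels of Mid1, S100a8 and Fpr2 is expected. Without SLC_2 each of these ended (adjusted p = 0.498, 0.63 and 0.308), and the Mid1 and S100a8 calls also ended without control_2 (0.0559, 0.0952) or SLC_1 (0.0866, 0.147). NK cells had 13 calls (12 higher, 1 lower), 6 without control_2, 0 without SLC_2, 231 without LPS_1 and 320 without LPS_2. With the top 6% of doublet scores left out they had 0, with Mid1 at 4.52, S100a8 at 2.81 and Fpr2 at 3.02, and with free-RNA-prone genes, these 3 among them, left out 2. T cells had 0 with such genes left out. Endothelial cells had 1, AA467197 (4.87 ± 3.11 to 141 ± 42.4 CPM, 4.64, SE 0.505, adjusted p = 0.0494, 55.8%), ending without control_1 (0.0967), control_2 (0.178), SLC_1 (0.0875) or SLC_2 (0.153); 3 genes passed without SLC_1, 0 without SLC_2 or either control, 402 without LPS_1 and 385 without LPS_2. At resolution 0.5 AA467197 did not pass, and it is among the free-RNA-prone genes. Monocytes and B cells had 0 in edgeR, with 479 and 899 genes at unadjusted p under 0.05 and 24 and 86 calls by DESeq2. In monocytes 1 gene passed without control_1, 158 without LPS_1 and 132 without LPS_2, and in B cells 112 without SLC_1, 95 without LPS_1 and 80 without LPS_2. Fabp4, a fatty acid binding protein, was at 29.6 ± 11.4 against 225 ± 12.8 CPM in monocytes (−2.81, adjusted p = 0.128).

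**Figure D3:**
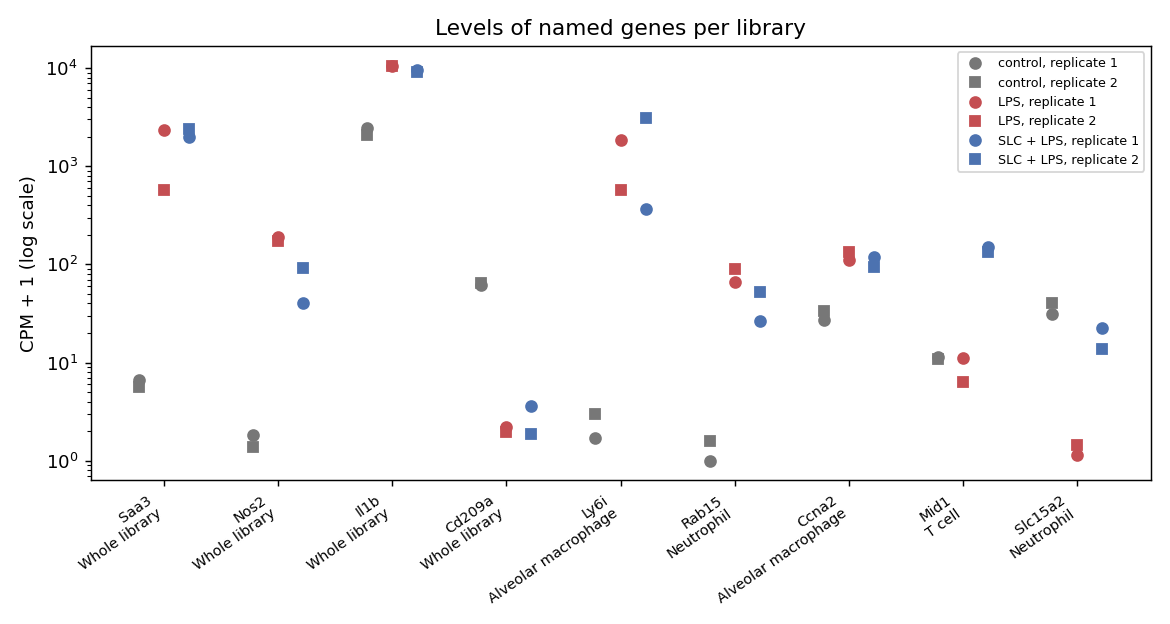
Levels of 9 named genes in each of the 6 libraries, as CPM + 1 on a log scale: Saa3, Nos2, Il1b and Cd209a in the whole library, Ly6i and Ccna2 in alveolar macrophages, Rab15 and Slc15a2 in neutrophils, Mid1 in T cells.

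Interferon-stimulated genes were higher as a list than in controls in 8 units (alveolar macrophage median 2.38, 10 of 32 rose, 23 adjusted over the list alone, adjusted p = 0.611 with an estimated correlation; T cell median 1.27, adjusted p = 1.42e-15, 15 of 29 adjusted over the list alone, adjusted p = 0.611 with an estimated correlation). MHC class I genes were higher in 7 (alveolar macrophage median 1.40, adjusted p = 0.000261, 5 adjusted over the list alone, adjusted p = 0.639 with an estimated correlation) and acute phase genes in 7 (endothelial median 2.46, adjusted p = 7.97e-09, 6 adjusted over the list alone, adjusted p = 0.611 with an estimated correlation). Cell cycle genes were higher in 6 (alveolar macrophages: 10 of 20 rose, 17 adjusted over the list alone, median 1.51, adjusted p = 8.93e-12, adjusted p = 0.611 with an estimated correlation). NF-kB genes were higher in 5 (endothelial median 1.12, adjusted p = 3.25e-09, 9 adjusted over the list alone, adjusted p = 0.611 with an estimated correlation) and oxidative phosphorylation genes in 5 (B cell median 0.51, adjusted p = 0.00344, adjusted p = 0.639 with an estimated correlation). MHC class II genes, which present antigen to helper T cells, were lower in 2 units (monocyte median −1.02, adjusted p = 0.00027, 4 fell adjusted over the list alone, adjusted p = 0.611 with an estimated correlation). No member passed over all genes, with H2-Eb1 at −1.39. cAMP and CREB targets were lower in 3 (monocyte median −0.48, adjusted p = 0.00856). Lower in neutrophils were adrenergic genes (−0.89, adjusted p = 0.0111, 3 fell adjusted over the list alone), cytotoxic genes (−1.02, adjusted p = 0.00856) and endothelial adhesion genes (−0.90, adjusted p = 0.0258). With an estimated correlation the lowest adjusted p over these was 0.611. Of the adhesion genes Thbd (−2.10) and Cd34 (−1.86, adjusted p = 0.0453) fell, each 100% expected from free RNA, and these calls ended without either control library or either SLC library (adjusted p 0.105 to 0.29), that of Cd34 also under the stricter cell filter. Alternative activation genes were higher in 3 (T cell median 1.09, adjusted p = 0.00687). Lymphocyte activation genes were higher in 3 and lower in 1 (NK cell median 1.09, adjusted p = 0.000109). Immediate early genes were higher in 2 (B cell median 0.76, adjusted p = 1.14e-05) and chemokine receptor genes higher in 1 and lower in 1 (endothelial median 0.31, adjusted p = 0.0066). With an estimated correlation each of these 4 lists was at adjusted p = 0.611 or more. Glucocorticoid targets passed in 0 units. Genes of free RNA were lower in 6 (medians −2.69 to −0.97; lowest adjusted p = 7.97e-09, adjusted p = 0.611 with an estimated correlation). In all 63 of 135 tests passed (47 up, 16 down), with 69 at unadjusted p under 0.05. Under an estimated correlation, with its few degrees of freedom, 0 passed. The split depends on single libraries, with 49 up and 8 down without SLC_1 and 29 up and 25 down without SLC_2. It was 31 up and 10 down of 108 tests with free-RNA-prone genes left out, and 39 up and 12 down of 125 with free RNA subtracted. In 20 tests, none passing, median, mean and test differed in sign.

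The LPS libraries enter both the comparison of LPS with control and that of SLC activation plus LPS with LPS, which forces a negative relation between their fold changes. Over 17930 genes in the whole library the covariance was −0.0426, against −0.139 (SD 0.00353 over 20 draws) simulated with unchanged groups and −0.224 expected from the spread of the LPS replicates, and 50% of genes had the same sign, against 33.6% simulated. For the 3411 genes with at least 50 CPM the covariance was −0.0485, with −0.0738 simulated and −0.12 from the replicates. The fold changes of the whole library were thus not more opposite than the shared libraries force, and single classes were not tested in this way. Slc15a2 in neutrophils, near 0 in the LPS libraries alone, had log2 fold changes of opposite sign in the 2 comparisons (−6.90, adjusted p = 0.00262, and 5.88).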

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

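Of the tests in this part, the one on a control library under an LPS label and the one on single libraries were chosen only after the result was seen. The setting without free-RNA-prone genes, used for the interferon list, was added after free RNA was seen to differ between libraries and after subtracting it was seen to leave almost no calls. Barcodes that were not kept as cells carry neutrophil RNA. Of the results above, only the free RNA estimates and the settings built on them rest on these barcodes. S100a8 there was at 1917 CPM in LPS_1, 4755 in LPS_2, 1863 in SLC_1 and 2162 in SLC_2, against 521 and 356 in the 2 controls. This difference between groups in barcodes not kept was not tested.

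Neutrophils of LPS_2 carried more Ngp, a granule protein gene of immature neutrophils, than those of LPS_1: 1318 against 620 CPM, with 2219 in control_1, 509 in control_2, 139 in SLC_1 and 184 in SLC_2. After thinning each neutrophil to 500 UMIs, which left out 0 cells in each library, 7.37% (6.64% to 8.15%) of neutrophils in LPS_2 and 3.63% (3.25% to 4.05%) in LPS_1 had an Ngp UMI, against 16.9% and 8.05% before thinning. Thinning moved the ratio of these shares little, from 2.10 to 2.03, and their intervals stay apart. At equal depth the shares thus still differ, which argues against depth per cell as the whole difference between these 2 libraries. Once the intervals are counted, 2.03 is not beyond the bound of 2 set beforehand, so that bound itself leaves depth open. Less dilution by free RNA allows a CPM ratio of 1.31, and the observed 2.12 is above it by less than the 2 times set beforehand, so this is left open too. Cluster 4, at most 1% of cells in either control, was 4.27% of LPS_2, which speaks against a control library under an LPS label.

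The lower interferon-stimulated genes in neutrophils after SLC activation plus LPS than after LPS are lowest in SLC_1. Cluster 0, led by interferon-induced genes, held 39.4% and 12.9% of neutrophils in LPS_1 and LPS_2. In SLC_1 and SLC_2 it held 6.86% and 42.0%. Mean log2 levels of the list were 4.61 and 4.71 in controls, 6.96 and 7.32 after LPS, and 5.16 and 6.96 after SLC activation plus LPS. The largest difference within a group, 1.81, exceeds the −1.08 between the group means, and SLC_1 lies below SLC_2 in each of the 7 classes. The result is therefore consistent with a difference between single mice or libraries. The median was −1.02 with all members and also without free-RNA-prone genes, so leaving these out did not move it. A gene counts as prone by its expected share in the group where it is highest. In LPS neutrophils the free RNA share was 26.3% in LPS_1 but only 3.56% in LPS_2, so few genes high after LPS can count as prone. This test therefore cannot decide on free RNA as the cause, which is left open.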

How the results depend on the processing

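Tests with free RNA subtracted, free-RNA-prone genes left out or the top 6% of doublet scores left out were chosen only after the result was seen, and all others before the data were examined. With 2 mice per group, single libraries decide most counts of changed genes, and tests of a 2-fold change found at most 17% of simulated changes in any unit and comparison. Calls of named genes numbered 55 for LPS against control. They numbered 39 for SLC activation plus LPS against control and 2 against LPS. Of the named genes that passed, 75 did so no longer without control_1, 87 without control_2, 5 without LPS_1 and 11 without LPS_2. The number was 41 without SLC_1, 48 without SLC_2 and 14 under the stricter cell filter. With free RNA subtracted it was 45, counting only genes of single classes that were still tested. Calls of genes no longer tested are not in the 45, and subtraction left almost no calls in any class. Among named genes and shares no call changed sign apart from the reversals named below, and DESeq2's size factors in edgeR moved no count by 1.5 times. Unless said otherwise the cause was not tested. Counts are given in the order whole library, neutrophil, monocyte, alveolar macrophage, T cell, NK cell, B cell and endothelial cell.

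For LPS against control (1438, 651, 30, 398, 1, 19, 1 and 3 genes), DESeq2 gave 3185, 1182, 61, 968, 99, 63, 41 and 106, and no low-count filter 4065, 1535, 237, 1566, 409, 291, 224 and 372. Leaving out 1 library gave 0 to 2864, 6 to 1800, 2 to 891, 0 to 1731, 0 to 753, 4 to 787, 1 to 63 and 0 to 1230. The stricter cell filter gave 258 in alveolar macrophages, 3 in T cells, 6 in NK cells, 8 in B cells and 0 in endothelial cells. With doublets kept T cells had 12, NK cells 39 and endothelial cells 62, and with the top 6% of doublet scores left out 3, 11 and 34.

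For SLC activation plus LPS against LPS (0, 1, 0, 0, 1, 0, 0 and 0 genes), DESeq2 gave 17, 12, 1, 2, 2, 1, 2 and 7, and no low-count filter 318, 69, 31, 30, 28, 16, 111 and 107. Leaving out 1 library gave 0 throughout in the whole library, and 0 to 563, 0 to 549, 0 to 379, 0 to 720, 0 to 534, 0 to 101 and 0 to 1044 in the classes. With the top 6% of doublet scores left out neutrophils had 2.

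For SLC activation plus LPS against control (2261, 444, 0, 384, 2, 13, 0 and 1 genes), DESeq2 gave 4128, 1047, 24, 1070, 102, 60, 86 and 88, and no low-count filter 4891, 1455, 49, 1613, 299, 157, 305 and 285. Leaving out 1 library gave 0 to 5014, 0 to 1915, 0 to 158, 0 to 2089, 0 to 326, 0 to 320, 0 to 112 and 0 to 402. The stricter cell filter gave 210 in alveolar macrophages, 4 in T cells and 10 in B cells. With doublets kept T cells had 4, B cells 2 and endothelial cells 39. With the top 6% of doublet scores left out NK cells had 0 and endothelial cells 5, and clustering at resolution 0.5 gave 2 in B cells and 0 in endothelial cells.

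Subtracting the expected free RNA, tried first, left 0 genes in each class but monocytes for LPS against control, and in each class that had calls for the other comparisons. Monocytes had 1 for LPS against control and 1 for SLC activation plus LPS against control. Of the 651 neutrophil calls for LPS against control 415 were still tested, 412 with the same sign, and the median absolute log2 fold change went from 2.22 to 3.08 while the median standard error went from 0.425 to 0.752. In alveolar macrophages 323 of 398 were still tested (321 with the same sign, 2.27 to 2.50, standard error 0.372 to 0.507). For SLC activation plus LPS against control 321 of 322 in neutrophils and 342 of 343 in alveolar macrophages kept their sign. Among the calls still tested, the median fold change did not shrink and the errors grew. Calls no longer tested are outside these medians, so they do not show why the calls were lost. Leaving out free-RNA-prone genes, tried second, gave 350 in neutrophils (302 higher, 48 lower), 5 in monocytes (4 higher, 1 lower), 258 in alveolar macrophages (187 higher, 71 lower), 0 in T cells, 4 in NK cells, 0 in B cells and 0 in endothelial cells for LPS against control. It gave 0 in T cells for SLC activation plus LPS against LPS. For SLC activation plus LPS against control it gave 291 in neutrophils (228 higher, 63 lower), 0 in T cells, 2 in NK cells and 0 in endothelial cells. Fewer genes were tested in this setting. Genes high after LPS are less easily left out by it, so the splits for LPS against control partly follow from the rule.

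Among the shares of cell classes, leaving out 1 library gave 2 to 14 changed classes for LPS against control, 0 to 4 for SLC activation plus LPS against LPS and 3 to 16 for SLC activation plus LPS against control (5, 0 and 12 with all libraries). TMM factors over classes gave 3 (2 higher, 1 lower), 0 and 4 (2 higher, 2 lower), and immune classes as the total 5, 0 and 10 of 11. The stricter cell filter gave 5 in the last comparison, and the top 6% of doublet scores left out gave 1 in the second. The monocyte share for LPS against control reversed to a log2 fold change of −1.58 without LPS_2 (range −1.58 to 2.10 over libraries left out), and the NK cell share for SLC activation plus LPS against control to 0.304 under TMM factors. Without LPS_1, Cxcl2 reversed in T cells (−1.48, range −1.48 to 1.44) and NK cells (−1.63, range −1.63 to 1.57) for LPS against control, and Adrb1 (1.48, range −0.97 to 1.48) and Tnf (1.51, range −1.01 to 1.51) in endothelial cells for SLC activation plus LPS against LPS.

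Of the gene lists, 50, 61 and 63 of 135 tests passed in the 3 comparisons and 0, 0 and 0 with an estimated correlation. That version has few degrees of freedom, so its 0 counts do not decide whether lists changed. For LPS against control leaving out 1 library gave 50 to 66, with 11 to 30 down, and subtracting free RNA 40 of 125 (33 up, 7 down). For SLC activation plus LPS against LPS leaving out 1 library gave 38 to 69, leaving out free-RNA-prone genes 40 of 108 (12 up, 28 down) and subtracting free RNA 39 of 125 (15 up, 24 down). For SLC activation plus LPS against control leaving out 1 library gave 54 to 69, with 29 to 49 up and 8 to 25 down, and leaving out free-RNA-prone genes 41 of 108 (31 up, 10 down). Fewer tests were run in these settings.

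The labels give the groups the same replicate numbers, with no word on pairing. With the replicate number as a block (replicate block), LPS against control had 248 genes in the whole library, 0 in alveolar macrophages, 0 in T cells, 7 in NK cells and 0 in endothelial cells, and 2 changed shares. SLC activation plus LPS against LPS had 4 genes in neutrophils, and SLC activation plus LPS against control 432 in the whole library, 19 in alveolar macrophages (17 higher, 2 lower), 5 in T cells and 0 in endothelial cells. The block takes 1 degree of freedom and moved no other count by 1.5 times. Among the values of named genes, 35 that passed did so no longer under the block. Correlations of the libraries' deviations between groups by replicate number were 0.0508, −0.104 and −0.182 over 17930 genes.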

Other observations

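A scan of 6706 genes asked which were apart by 2-fold between the libraries of 1 group and all others in all but at most 1 of at least 6 classes. It found 24 genes higher in controls (among them Dcn, Gsn, Clec3b, Inmt, Ltbp4, Prelp and Scgb3a2 in 7 of 7 classes), and 5 lower (Saa3, Inhba, Nos2, Cxcl9 and Ly6i). The scan took no account of free RNA. From it 42.9% to 67.4% of Inmt over 5 classes, 64.5% of Ltbp4 in monocytes, 50.5% of Gsn in endothelial cells and 100% of Scgb3a2 in neutrophils, monocytes and alveolar macrophages is expected, as is 45.2% of Saa3 in neutrophils. Genes of the free RNA list were lower in 8 units after LPS. Given the parts expected from free RNA, the scan does not show in which cells the genes found by it differ. A single gene, Slc15a2, was lower in the LPS group (6 of 6 classes), and a single gene, Mid1, was higher after SLC activation plus LPS (6 of 7). Slc15a2 was at 23.22 and 24.86 CPM in T cells of controls, 1.355 and 0.592 after LPS, and 61.65 and 25.47 after SLC activation plus LPS. In barcodes not kept it was at 31.9, 33.8, 2.78, 5.78, 39.6 and 22.8 CPM from control_1 to SLC_2. The scan was designed after Mid1 had been noticed. An inherited difference between the mice of the groups was not tested for Slc15a2, and the design does not separate it from the treatments.

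Both tests on Mid1 in this part were chosen only after the result was seen. Mid1, which spans the pseudoautosomal boundary in laboratory mice, was higher after SLC activation plus LPS than in the other groups in each class tested, with 150 and 133 CPM in T cells against 5.329 to 10.449 in the others. The level expected from free RNA, capped at the observed level, was 97.0% of it as a median over classes, as free RNA as the source would give. In SLC_2 neutrophils, however, 35.5% of the 498 CPM in barcodes not kept far exceeds the 32.4 CPM observed. The estimate overshoots there, so the median does not settle the source. Mid1 was also at 205 and 498 CPM in the barcodes not kept of the SLC libraries, against 23.9 to 37.8 in the others. Free RNA thus leaves the excess itself unexplained. An inherited difference between the mice could give the same pattern: in 6 classes both SLC libraries lay beyond 2 times the other 4, but the design cannot separate this from the treatment.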
